A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

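Total RNA (about 20 ug per sample, from cells at an OD600 of 0.5 to 0.7) was labelled with biotin and hybridised to single-colour Affymetrix yeast arrays, 2 of wild type and 2 of the H3 mutant, per the labels' protocols. The deposited values are intensity values on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. From the values, both wild-type arrays have a trimmed mean (2 to 98 percent) of 124.9, and the mutant arrays have 106 and 87.5. All values of each array (100%, tolerance 0.01) are whole multiples of its smallest step, 0.1 in wild type and 0.0849 and 0.07 in the mutant. The mutant arrays thus carry further constants of 0.849 and 0.7 (log2 -0.24 and -0.51), and without them their trimmed means are 124.9 too. The origin of the constants is not given in the sources used here. A constant on each array changes no ratio within an array, but it moves changes between groups, and once a pseudocount is added it moves bright genes more than dim ones. Changes are therefore given on median-scaled values, where the median of all genes is 0.018, except where the values as deposited are named. Deposited medians were 37.3 and 38.4 in wild type and 29.7 and 27.8 in the mutant.

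Each array was divided by its median over all 9335 probe sets and multiplied by the mean of the 4 medians. A pseudocount of 5.71, the 20th percentile of all scaled values, was added before log2, so that changes of dim genes are understated. Detection calls were not used here. The platform annotation gives 1 gene symbol for 6504 probe sets, several for 328 and none for 2443, and 60 are controls. All 6504 were matched through their gene number to the reference gene table of assembly R64, and 0 symbols changed. No genome coordinates are given. For each of 5656 genes 1 probe set was tested, without a suffix for shared sequence where there was such a set and then the brightest. This left 211 genes on suffixed probe sets. In a fit of all 9335 probe sets, 0 of 315 genes with more than 1 probe set had sets called in opposite directions. With 11 sets called higher and 21 lower in that fit, this says little about their agreement.

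Groups were taken from the sample titles. The comparison of mutant minus wild type used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided), with Benjamini-Hochberg adjusted p under 0.05 and no minimum fold. No replicate block was used, since the labels do not say that a number marks a shared culture or day. Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists. With a correlation estimated for each list, camera tests on 2 residual degrees of freedom, and 0 of the 15 calls held (smallest adjusted p 0.79). The camera p-value rose even where the estimate was small, as for COS genes (correlation -0.05, p from 5.61e-06 to 0.0424). A call lost in this way therefore does not show that correlation between genes had caused it. By fry, which tests whether genes of a list move on balance one way and does not compare them with other genes, 0 lists passed (6 at an unadjusted p under 0.05, smallest adjusted p 0.12). Its mixed test, of changes in either direction, called 17 lists (smallest adjusted p 0.027). The list of outermost ORFs was taken from systematic names.

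Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest rises and 12 largest falls among changed genes whose arrays do not overlap, histone genes, up to 4 members in the direction of each list past the threshold, up to 2 changed members of other lists, GAL1, GAL7, GAL10, SIR2, SIR3, SIR4, SET1, SET2 and DOT1. Alternatives were other scalings, pseudocounts, a filter on dim genes, probe set rules, other variance models, thresholds, a replicate block, leaving out each array, and other list tests. With an array left out, the lone array of a group is assumed to vary like the other group. Data were simulated with wild-type levels and with noise fitted to the arrays by level, with a further spread of SDs between genes. Of genes changed 2-fold 63% were called, and of genes changed 4-fold 97%. Of 5456 unchanged genes 5 were called, and 0 of 5656 genes when none was changed. These folds apply to signal plus pseudocount, so they do not give the share called for that fold of signal in dim genes. A shifted list was found, and 0 of 20 unshifted lists were called. The noise was drawn independently for each gene, so the simulation does not check error rates where genes vary together. Estimated correlations in the real lists reached 0.64 for auxotrophic marker genes and 0.63 for ribosomal proteins.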

Results

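Transcript levels were measured on 4 single-colour Affymetrix arrays from budding yeast (Saccharomyces cerevisiae), 2 from wild-type cells and 2 from cells whose histone H3 carries arginine in place of lysines 4, 36 and 79. These lysines are the H3 residues methylated by Set1, Set2 and Dot1. Per the labels, cultures grown in galactose were moved to glucose for 9 h, which turns off a wild-type H3 gene so that the mutant H3 becomes the only H3 made. The series text describes the arrays of each group as replicate cultures. The question is which genes depend on the mutated lysines. After median scaling, log2 values of the 2 wild-type arrays correlated across 5656 genes with r = 0.986, and those of the 2 mutant arrays with r = 0.983. Pairs from different groups gave r = 0.959 to 0.975. The SD of the log2 difference was 0.306 between the wild-type arrays, 0.341 between the mutant arrays and 0.404 to 0.519 across groups. The number of arrays limits the precision, and an exact permutation test of 2 against 2 cannot give p under 0.33. Signal ratios of the 3' over the 5' probe set of ACT1 were 1.14 and 1.13 in the wild-type arrays and 1.19 and 1.23 in the mutant arrays. The same ratio was less even for SPT15, at 2.41 and 0.63 in wild type and 3.85 and 2.17 in the mutant, and for SRB4, at 2.26 and 8.29 in wild type and 4.62 and 3.43 in the mutant. All 10 control probe sets for ribosomal RNA were higher in both mutant arrays, with a median log2 change of 1.43, and the 9 hybridization controls had a median of 0.04.

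Histone H3 is encoded by HHT1 and HHT2, and each of its 3 probe sets is annotated to both genes, so no value belongs to either gene alone. The H3 probe set marked by its suffix as shared sequence gave 490.1 ± 9.46 in wild type and 133 ± 15.8 in the mutant (SD, n = 2), a log2 change of -1.84 ± 0.16 (SE; limma adjusted p = 0.0364 in a fit of all 9335 probe sets). The brightest H3 probe set gave 2727 ± 524 and 3941 ± 1934, a log2 change of 0.45 (SE 0.43, adjusted p = 0.619), and the dim probe set gave 6.18 and 7.2. The H3 probe sets therefore disagree, and none is known to cover a mutated codon, so they do not check the labels. Without mutant replicate 1 the change of the shared-sequence set was -1.96 and that of the brightest set was -0.07. Without mutant replicate 2 the change of the shared-sequence set was -1.73 and that of the brightest set was 0.97. The probe set shared by the H4 genes HHF1 and HHF2 had a log2 change of 0.72 (adjusted p = 0.183), and the 2 shared by the H2A genes HTA1 and HTA2 had 0.04 and -0.11. None of the 5 histone genes with a probe set of their own passed the test over all genes or adjusted over the list alone. Their log2 changes were -0.40 for HTZ1, 0.45 for HHO1, 0.17 for CSE4, -0.17 for HTB2 and -0.12 for HTB1 (camera adjusted p = 0.894 for the list).

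In the mutant, 58 genes rose and 48 fell at a Benjamini-Hochberg adjusted p under 0.05 in limma. The largest rise was that of URA3, an enzyme of uracil synthesis, from 9.18 ± 1.24 to 247 ± 29.4 (SD, n = 2), a log2 change of 4.08 ± 0.17 (SE; adjusted p = 0.000298). The marker genes of the strains are not given in the labels used here, so a difference in genotype at URA3 is not excluded. The phosphate transporter gene PHO84 rose from 34.4 ± 2.59 to 150.2 ± 43.1 (log2 1.93 ± 0.21, adjusted p = 0.0202), and the acid phosphatase gene PHO5 of the same regulon rose from 108 ± 9.35 to 299 ± 72.2 (log2 1.40, adjusted p = 0.0338). The largest fall was that of HO, the endonuclease of mating-type switching, from 150.7 ± 4.59 to 27.6 ± 0.949 (log2 -2.23 ± 0.15, adjusted p = 0.00413). The purine synthesis gene ADE8 fell from 585 ± 25.6 to 169 ± 32.7 (log2 -1.77, adjusted p = 0.0202).

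The other rises among the 12 largest were those of PUL3 (log2 1.76), the inositol pyrophosphatase gene SIW14 (1.66), YMR085W (1.60), the metallothionein gene CRS5 (1.59), SAS4, a subunit of an H4 acetyltransferase complex (1.57), YOL036W (1.53), HEF3, an elongation factor gene (1.53), the protein kinase gene PKH2 (1.51), YOR062C (1.5) and YKR104W (1.48). Their limma adjusted p ran from 0.0202 for YMR085W and PKH2 to 0.0479 for YOL036W. YMR085W read 0.655 in wild type, and PUL3 and PKH2 read 5.61 and 5.62, near or below the pseudocount of 5.71, so that their changes understate the ratio of signals. The other falls were those of COS7 (log2 -1.89), HUA1 (-1.69), CDC26, a subunit of the anaphase-promoting complex (-1.63), GON7 (-1.60), BNA1 of NAD synthesis (-1.60), COS8 (-1.59), the rRNA methyltransferase gene BMT5 (-1.54), RIB4 of riboflavin synthesis (-1.50), AIF1 (-1.47) and COS4 (-1.44). Their adjusted p ran from 0.0202 for COS7, HUA1, CDC26, GON7 and COS4 to 0.0430 for BMT5. The 2 mutant arrays lay on the same side of both wild-type arrays for all 106 changed genes, which a called change makes likely by itself. The same held for 55.2% of all genes, where chance gives 33.3%.

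**Figure D1:**
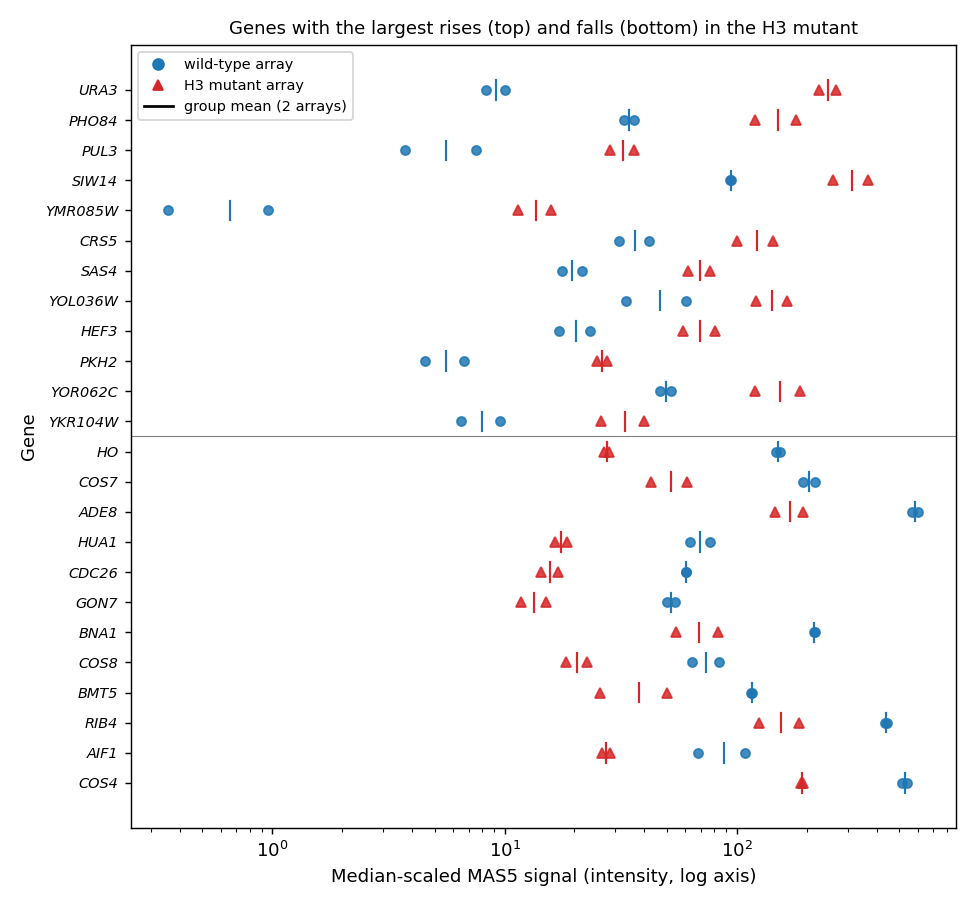
Median-scaled MAS5 signal (horizontal log axis, intensity) of the 12 genes with the largest rise and the 12 with the largest fall, with wild-type arrays as circles, mutant arrays as triangles and group means of 2 arrays as ticks. By the rule that chose these 24 genes, no mutant array overlaps a wild-type array. URA3 has the widest gap, from means of 9.18 to 247.

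The counts rest on all 4 arrays and on 1 probe set per gene. In the limma fit of all 9335 probe sets, 11 were called higher and 21 lower. Without mutant replicate 1 or without mutant replicate 2, 0 genes passed. Without wild-type replicate 1, 196 genes were higher and 85 lower, and without wild-type replicate 2, 122 and 59. On the values as deposited, where the median of all genes was -0.319 in place of 0.018, 66 genes were higher and 1065 lower, a share of 5.8% higher against 54.7%. In total 1313 genes had an unadjusted p under 0.05, and a plain test with equal variances for each gene alone called 0 genes higher and 1 lower (825 at an unadjusted p under 0.05).

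Genes of the COS list, most of which lie near chromosome ends, had lower signals in the mutant. The list was made by name and held COS111, the only member above 0 (log2 0.14), with signals below the pseudocount. Of 8 measured members 3 fell over all genes tested and 5 adjusted over the list alone, and the list median was -0.89. COS7 fell from 205 ± 17.4 to 51.9 ± 13.0, COS4 from 528 ± 22.1 to 191 ± 3.01 and COS8 from 73.6 ± 13.9 to 20.5 ± 3.02 (SD, n = 2), while COS10 had a log2 change of -0.99 (adjusted p = 0.0785). The list shifted down by camera (adjusted p = 5.54e-05). With an estimated correlation, here -0.05, camera gave an adjusted p of 0.79, on 2 degrees of freedom. COS7 and COS4 were read by probe sets whose suffix marks shared sequence. The 7 COS probe sets without such a suffix, COS111 among them, had a median of -0.39 with an SD of 0.57. Over the 5 whose mean signal exceeds the pseudocount, which leave COS111 out, the median was -0.79 with an SD of 0.53, a selection made after seeing the data.

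The PAU list also held DAN and TIR genes and was not confined to chromosome ends. Its median log2 change was 0.35 over 16 measured members, and none passed over all genes while 5 rose adjusted over the list alone. PAU7 had 0.80, PAU19 0.63, PAU23 0.83 and DAN4 0.58 (camera adjusted p = 0.022, and adjusted p = 0.79 with an estimated correlation). The call was lost without wild-type replicate 1 (adjusted p = 0.0968) and without suffixed probe sets (adjusted p = 0.436). The outermost 10 ORFs of each of the 32 chromosome arms, 320 in all, had a median log2 change of 0.011 (camera adjusted p = 0.975), at percentile 16.9 of 10000 random lists matched on level. Of these ORFs 11 rose and 13 fell, against 29 and 24 adjusted over the list alone. The falls held COS7 and BNA6, a gene of NAD synthesis, which fell from 296 ± 8.73 to 109.5 ± 7.85. The 26 genes for Sir silencing factors and H3 methyltransferase machinery did not shift (median -0.03, camera adjusted p = 0.894, none passing). Beside the methyltransferases this list held genes such as RAD6, BRE1, PAF1, JHD1 and JHD2. Log2 changes were 0.28 for SIR2, 0.33 for SIR3, 0.11 for SIR4, -0.02 for SET1, 0.01 for SET2 and -0.27 for DOT1, with adjusted p from 0.244 to 0.983, and SET2 read 1.27 and 1.37, below the pseudocount.

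The lists of general stress, sulfur, iron and glucose-repressed carbon metabolism genes shifted up by camera at its preset correlation, with 37 of 44, 18 of 23, 23 of 29 and 30 of 34 members above 0. None of these 4 calls held with an estimated correlation (adjusted p = 0.79 for each with an estimated correlation) or by directional fry, and few single members passed over all genes. The median log2 change of the stress-induced genes was 0.35, with 2 rising over all genes and 6 adjusted over the list alone. HSP78, a mitochondrial chaperone, rose from 52.6 ± 8.87 to 107 ± 2.94 and the polyubiquitin gene UBI4 from 247 ± 4.39 to 465 ± 33.6, while GLC3 had 0.83 and RTN2 0.73 (camera adjusted p = 1.19e-05, and adjusted p = 0.79 with an estimated correlation). Of 23 sulfur and methionine genes 4 rose over all genes, and 11 rose and 1 fell adjusted over the list alone. The 4 were MET2 (log2 1.05), MET3 (0.92) and the sulfate transporter genes SUL1 (0.90) and SUL2 (0.92), and the list median was 0.40 (camera adjusted p = 5.54e-05, and adjusted p = 0.79 with an estimated correlation).

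Of 29 iron regulon genes none passed over all genes, while 12 rose and 2 fell adjusted over the list alone. FIT2 had a log2 change of 1.97 with an SE of 0.42, HMX1 0.94, ARN1 0.91 and FRE2 0.85, and the median was 0.36 (camera adjusted p = 0.00272, and adjusted p = 0.79 with an estimated correlation). Among 34 glucose-repressed genes of carbon metabolism only the maltose transporter gene MAL11 rose over all genes (0.88), and 9 rose and 1 fell adjusted over the list alone. CIT2 had 1.22, IDP2 0.88 and FBP1 0.82, and the median was 0.30 (camera adjusted p = 0.000697, and adjusted p = 0.79 with an estimated correlation).

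Of 88 ribosome biogenesis genes 74 lay below 0 in the mutant, the median was -0.25, and 2 fell both over all genes and adjusted over the list alone. KRR1, of small-subunit assembly, fell from 114 ± 4.20 to 57.2 ± 5.94, and RIX1, of pre-rRNA processing, from 193 ± 3.84 to 107 ± 1.29 (SD, n = 2), while DBP8 had -0.71 and REX4 -0.77. The list shifted down by camera (adjusted p = 2.16e-07). With an estimated correlation, here 0.13, camera gave an adjusted p of 0.79, on 2 degrees of freedom. The median of the stress genes minus that of the ribosome biogenesis genes was 0.49 to 0.78 higher in a mutant than in a wild-type array over the 4 pairs, and differed by 0.24 between the wild-type arrays and by -0.07 between the mutant arrays. The rRNA control probe sets moved up with the same arrays, by a median of 1.43. Ribosomal protein genes, 81 in all, had a median of 0.00 (camera adjusted p = 0.894), but gave -0.235 relative to all genes without mutant replicate 1 (adjusted p = 1.31e-06) and 0.175 without mutant replicate 2 (adjusted p = 0.00344).

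**Figure D2:**
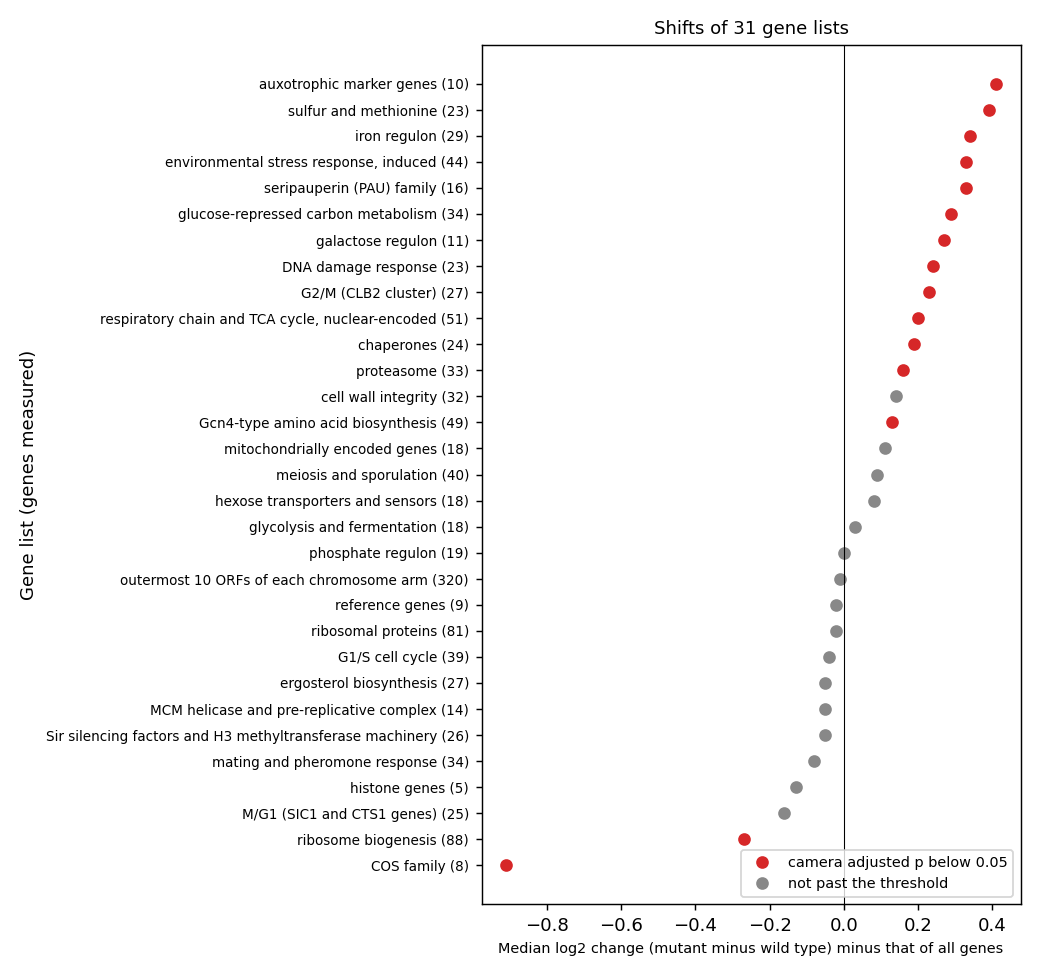
Median log2 change of each of 31 gene lists, mutant minus wild type, after subtracting the median of all genes (horizontal axis), with the number of measured genes in parentheses. The 15 lists with a camera adjusted p under 0.05 are red, 13 above and 2 below 0, and COS genes lie lowest at -0.91.

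Upward shifts past the camera threshold came from 8 more lists. Of 49 amino acid synthesis genes of the Gcn4 type ARG3 (log2 0.96) and ARG4 (0.86) rose, over all genes and adjusted over the list alone, and ARG1 had 0.96 and TRP3 0.54 (median 0.15, camera adjusted p = 0.0294, and adjusted p = 0.79 with an estimated correlation). That call was lost without wild-type replicate 1 (adjusted p = 0.052), wild-type replicate 2 (adjusted p = 0.22) and mutant replicate 1 (adjusted p = 0.0869). Of 10 auxotrophic marker genes URA3 rose over all genes and 2 adjusted over the list alone. MET17 had 0.78 and HIS3 0.58, and TRP1 had 0.80 but read 0.309 in wild type and 4.85 in the mutant, both below the pseudocount, and the median was 0.43 (camera adjusted p = 0.0216, and adjusted p = 0.84 with an estimated correlation). Without URA3, a check chosen after seeing the data, the adjusted p was 0.139.

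Among 11 galactose genes none passed over all genes and 1 rose adjusted over the list alone. GCY1 had a log2 change of 0.96, MTH1 0.57, GAL1 0.45, GAL7 0.38 and GAL10 0.34, and GAL1 read 4.55 in wild type and 8.27 in the mutant. The median was 0.29 (camera adjusted p = 0.0288, and adjusted p = 0.79 with an estimated correlation). The call was lost without wild-type replicate 2 (adjusted p = 0.19), without mutant replicate 2 (adjusted p = 0.259), with the replicate block (adjusted p = 0.0581) and, chosen after seeing the data, without GCY1 and MTH1 (adjusted p = 0.18).

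Of 24 chaperone genes none passed over all genes and 1 rose adjusted over the list alone. HSP30 had 0.83, STI1 0.79, SSE2 0.49 and CPR6 0.49, with a median of 0.21 (camera adjusted p = 0.0305, and adjusted p = 0.84 with an estimated correlation). It was lost without wild-type replicate 1 (adjusted p = 0.262), wild-type replicate 2 (adjusted p = 0.193) and mutant replicate 1 (adjusted p = 0.119), and with the replicate block (adjusted p = 0.102). None of 33 proteasome genes passed over all genes or adjusted over the list alone, with PRE6 at 0.87, RPN8 at 0.96, PRE7 at 0.54, RPN4 at 0.52 and a median of 0.17 (camera adjusted p = 0.0258, and adjusted p = 0.79 with an estimated correlation). It was lost without wild-type replicate 1 (adjusted p = 0.0623) and wild-type replicate 2 (adjusted p = 0.19).

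None of 51 nuclear genes of the respiratory chain and TCA cycle passed over all genes or adjusted over the list alone. ATP14 had 0.55, ATP4 0.51, CYC7 0.43 and ATP7 0.38, with a median of 0.22 (camera adjusted p = 0.0115, and adjusted p = 0.84 with an estimated correlation). That call was lost without wild-type replicate 1 (adjusted p = 0.0623), wild-type replicate 2 (adjusted p = 0.22) and mutant replicate 1 (adjusted p = 0.0631).

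None of 27 G2/M genes of the CLB2 cluster passed over all genes or adjusted over the list alone, with IQG1 at 0.48, MYO1 at 0.47, ALK1 at 0.45, CHS2 at 0.43 and a median of 0.25 (camera adjusted p = 0.0288, and adjusted p = 0.79 with an estimated correlation). The call was lost without wild-type replicate 1 (adjusted p = 0.354), wild-type replicate 2 (adjusted p = 0.142) and mutant replicate 2 (adjusted p = 0.0813), and with the replicate block (adjusted p = 0.169). Of 23 DNA damage genes none passed either way, with PHR1 at 0.66, MSH5 at 0.64, DIN7 at 0.50, RAD54 at 0.47 and a median of 0.26 (camera adjusted p = 0.0458, and adjusted p = 0.79 with an estimated correlation). It was lost when any 1 of the 4 arrays was left out, with adjusted p of 0.262 and 0.0768 without wild-type replicates 1 and 2 and of 0.0558 and 0.113 without mutant replicates 1 and 2, with the replicate block (adjusted p = 0.114) and with quantile normalization (adjusted p = 0.0691). On the values as deposited the adjusted p was 0.0696 for the Gcn4-type and for the DNA damage genes, 0.058 for chaperones, 0.166 for the proteasome, 0.0539 for the respiratory chain and TCA cycle and 0.177 for the G2/M genes.

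The remaining lists did not pass. Phosphate regulon genes had a median of 0.02 over 19 members with PHO84 and PHO5 rising, over all genes and adjusted over the list alone (camera adjusted p = 0.189). The cell wall gene PIR3 rose from 275 ± 5.91 to 619.6 ± 123 (log2 1.14, adjusted p = 0.0430), the only gene past the test over all genes in the cell wall integrity list (median 0.16, camera adjusted p = 0.192) and in the M/G1 list (median -0.14, camera adjusted p = 0.189). Adjusted over the list alone, 2 and 1 genes rose there. The M/G1 list passed only without mutant replicate 1 (adjusted p = 0.0206). Medians and camera adjusted p were -0.06 and 0.448 for mating and pheromone genes, 0.10 and 0.341 for meiosis and sporulation, -0.03 and 0.597 for G1/S genes, 0.10 and 0.894 for hexose transporters, and 0.12 and 0.31 for mitochondrially encoded genes. On the values as deposited, the meiosis and the mitochondrially encoded lists passed, upward, each with an adjusted p of 0.0238. Glycolysis and fermentation genes gave 0.05 and 0.894, passing only without mutant replicate 2 (adjusted p = 0.0277), ergosterol genes -0.03 and 0.827, and reference genes 0.00 and 0.975. The MCM and pre-replicative complex genes had a median of -0.03 but a mean of 0.06 (camera direction up, adjusted p = 0.975). Adjusted over the list alone, 2 mating genes rose and 3 fell, 1 hexose transporter gene fell and 1 ergosterol gene fell. The mating-type loci had 1 measured gene, HMRA1 (log2 0.14), and the Y' helicases 0, so these lists were not tested.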

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

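The tests of explanations in this part, namely unsuffixed COS probe sets, the bootstrap interval of the outermost ORFs, whole multiples of a step and poly(A) controls, were chosen only after the results were seen, while leaving COS and PAU genes out of the outermost ORFs and using the values as deposited were planned. Control probe sets for ribosomal RNA and URA3, which are not among the genes compared in the report, gave signals above the wild-type level. The 10 probe sets for ribosomal RNA had a median log2 change of 1.43 and were higher in both mutant arrays, with limma calling 4 of them in a fit of all probe sets. The URA3 control probe set had a log2 change of 4.31, beside 4.08 for the URA3 gene probe set, and the labels used here do not give the strains' marker genes, so a URA3 marker present in the mutant strain alone was not tested and stays open beside a response to the mutant H3.

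COS probe sets were lower in the mutant, with medians of -1.61 over 7 probe sets that name several genes and -0.90 over 16 that name 1 gene, and so were 22 of 24 probe sets for the Y' elements next to the telomeres (median -1, 1 called). The 304 outermost ORFs without COS and PAU genes had a median of 0.015 (95% bootstrap interval -0.02 to 0.07). This argues against a fall of all outermost ORFs that have a probe set of their own. Genes read only by probe sets that name several genes, the Y' helicases among them, were not in this list. A fall confined to the very ends is therefore not excluded. Probe sequence shared between near-identical COS genes stays open, so that fewer genes may have fallen than probe sets show. The 7 unsuffixed sets had a median of -0.39 with an SD of 0.57, but 2 of them read below the pseudocount and could hardly show a fall. These 2 were the COS111 set and a COS9 set. The other 5, among them COS8 at -1.59, COS10 at -0.99 and COS6 at -0.79, had a median of -0.79 with an SD of 0.53. The median plus the SD was -0.27, which just misses the bound of -0.3 chosen to argue against shared sequence. No Y' probe set names 1 gene, so that part could not be tested, nor were different copy numbers in the strains or an effect of the H3 mutation, which stay open.

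As deposited, the median of all genes was -0.319 in the mutant. A constant applied to each mutant array after MAS5 accounts for steps below those of wild type, since 100% of the values of both arrays are whole multiples of such a step, but why it was applied is unknown. A smaller amount of mRNA per total RNA may be what the constants encode. Between groups, the poly(A) controls differed by a median log2 of 0.01 as deposited and of 0.41 after median scaling. As deposited, replicate 1 exceeded replicate 2 by a median of 0.64 in wild type and 0.77 in the mutant. Those same-group differences exceed the shift of all genes unless the numbers pair the arrays, which the labels do not say. The poly(A) controls therefore cannot decide. Statements on the total amount of mRNA are therefore not made.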

How the results depend on the processing

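The trimmed-mean scaling, the lists without named members and the 2 lists chosen after the values were seen were added after seeing the data. Of the 106 changed genes 52 were called in each of 11 other limma settings with all 4 arrays. These 11 do not count the plain test of each gene alone or the other thresholds. All 106 kept their direction as deposited, with quantile normalization, with equal trimmed means and with the average of a gene's probe sets, while settings that leave out an array or change the variance model could not turn it, as the arrays of these genes do not overlap. The main counts were 58 higher and 48 lower. Values as deposited gave 1065 lower, eBayes without trend 30 lower, equal trimmed means 38 higher and robust eBayes 159 higher and 118 lower. An adjusted p under 0.1 gave 249 and 206, a minimum of 2-fold 38 higher, and the plain test of each gene alone 0 higher and 1 lower. Leaving out 1 array gave 0 to 196 higher and 0 to 85 lower, with 0 without either mutant array. The cause was not tested.

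The replicate block gave 425 genes higher and 283 lower. Replicate deviations of same-numbered arrays correlated across genes at r = -0.015, so the gene signals show no pairing by number. The poly(A) controls did differ alike by number, with replicate 1 minus replicate 2 at 0.64 in wild type and 0.77 in the mutant as deposited. Whether a number marks a shared preparation therefore stays open. The block fit leaves 1 degree of freedom fewer.

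Of 31 lists 13 were up and 2 down. COS, stress, ribosome biogenesis, sulfur, iron, glucose-repressed and auxotrophic marker lists were called in all 14 other settings of arrays, scaling and probe sets. Leaving out 1 array gave 6 to 12 lists up and 2 to 4 down. With an estimated correlation and by directional fry, 0 lists were up and 0 down, and mixed fry called 17 in either direction. Counting lists with more members past the threshold over the list alone gave 5 down, and adding the NAD and purine lists 4 down. Ribosomal protein genes turned to 0.175 without mutant replicate 2 and gave -0.235 without mutant replicate 1. The cause was not tested.

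The median of the outermost ORFs relative to all genes was -0.007, 0.045 as deposited, and -0.026 to 0.018 with 1 array left out. The dim H3 probe set, at -0.05, gave 0.02 with the pseudocount at the 40th percentile and -0.78 to 0.68 with 1 array left out. With 1 array left out, the shared-sequence H3 probe set gave -1.96 to -1.73 and the brightest -0.07 to 0.97. Signals near the pseudocount limit what can be read from dim genes.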

Other observations

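The NAD and purine lists and the tests of changed genes at chromosome ends and of gene length were chosen only after the results were seen, while the list of outermost ORFs was fixed beforehand. Of 15 genes of NAD synthesis and nicotinic acid uptake 11 lay below 0 and 4 above in the mutant, and BNA1, BNA6 and the nicotinic acid transporter gene TNA1 fell, with log2 changes of -1.60, -1.39 and -1.40. The list median was -0.37 (camera p = 0.000262, and p = 0.061 with an estimated correlation), while BNA2 had 0.46, BNA3 0.42, NRK1 0.26 and PNC1 0.13. Of 27 purine and folate synthesis genes 18 lay below 0 and 9 above. ADE8, AAH1 and FOL2 fell (log2 -1.77, -1.20 and -1.04), and the median was -0.26 (camera p = 0.00178, and p = 0.32 with an estimated correlation). As these lists were chosen for genes already seen to fall, their p-values are too small.

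Among the 320 outermost ORFs 24 changed (7.5%), against 79 of 5158 other ORFs (1.5%; Fisher's exact test, two-sided, p = 2.8e-09, with genes not independent). As a ratio of the shares the excess was smaller in 5 other settings: 25.6% against 19.2% as deposited, 20% against 11.7% with the replicate block, 12.8% against 4.3% with robust eBayes, 10.3% against 4.5% without wild-type replicate 1 and 10.3% against 2.7% without wild-type replicate 2, while eBayes without trend gave 5.6% against 1%. The 11 that rose include PHO84, PGU1, PCA1, AQY3, AAD10, SUL1 and MAL11, and the 13 that fell include BNA6, URA1, ELP6, PFA3 and KRR1. PHO84, SUL1, MAL11, BNA6 and KRR1 are members of the phosphate, sulfur, glucose-repressed, NAD and ribosome biogenesis lists. Whether membership in such lists accounts for the excess was not tested. This was tested only with median scaling and all 4 arrays. There the signal level of these ORFs and the COS and PAU families alone are each argued against. So is shared probe sequence as far as a suffix marks it, while unsuffixed probe sets were not checked by sequence. Of 10000 level-matched random lists none held as many changed genes, with up to 16, 14 and 15. Counting the list itself among the draws, the share was 1e-04 for each, the smallest these draws can give. The draws take genes as independent and do not permute arrays, so the share does not measure the spread between arrays. The hypothesis that the H3 mutation may disturb expression at chromosome ends in both directions stays open beside a difference between the strains there, which was not tested, and without either mutant array no gene is called.

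A second hypothesis was that transcription may start inside long genes in the mutant, raising their signal. Rank correlations of log2 difference with gene length over 5486 coding genes were 0.053 to 0.138 in the 4 mutant and wild-type pairs, but 0.061 between the 2 mutant arrays, so the smallest does not exceed the spread between replicates and the test decides nothing. From the shortest to the longest of 4 length classes, median log2 changes were 0.001, -0.031, 0.052 and 0.08. In the same order 7, 17, 13 and 18 genes rose and 11, 22, 9 and 4 fell.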
